A study of Mus musculus with 10 samples.

How the data were processed

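Ventricular tissue of 5 sham-operated and 5 naive C57BL/6 mice was frozen and its RNA extracted, poly(A) RNA was selected with oligo(dT) and fragmented chemically, and single-end libraries that do not mark strand were made, per the labels' protocols. The deposited values are raw counts of reads per Ensembl gene, made with HTSeq on GRCm38, per the file headers, and they were not pooled or normalised. Bowtie2, TopHat2 2.1.1, HTSeq, DESeq and edgeR are named without their roles in the submitters' processing notes. The annotation release, the counting mode and the strand setting are not given in the sources used here. The deposited table also holds the GC content of each gene in percent, per the file headers, which was used only for a GC correction. Without strand, reads of overlapping genes on opposite strands cannot be told apart, and reads of near-identical genes may be split or lost, so such genes are uncertain.

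The table held 41264 rows, of which 574 repeated an Ensembl identifier with identical counts and were collapsed, leaving 40690 genes. Every row named a gene and all 10 sample columns were used. Library totals ran from 9683181 to 21537135 counts, and a floor of 3 counts per library is given in CPM for the deepest and the shallowest library; it covers counting error only, since PCR copies are not independent molecules. Groups were taken from the treatment labels. Nothing beyond the separate samples says how the mice were housed, operated or collected, so p-values measure the spread between these 5 and 5 samples.

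Genes were kept by filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), which left 13622, and were scaled with TMM factors. The main test was edgeR's quasi-likelihood F test with robust estimation on a design with the group alone, at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are sham against naive, with the standard error taken as the size of the log2 fold change over the square root of F, and CPM values are TMM-normalised and given as mean ± SD. Coordinates are those of GENCODE M21 on GRCm38, the build of the counts, matched by Ensembl identifier for all 161 named genes; 4 of these shared over 20% of their exon bases with another gene.

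Before the data were examined, 32 gene lists with 694 memberships were fixed for pathways and cell types that a ventricle after surgery could show; 103 memberships were not tested because the gene was too low or absent. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 32 lists, beside camera with an estimated correlation and fry. Directional fry, which asks whether a list's genes move one way on balance, passed for 21 lists, and its mixed form, which asks for change in either direction, for 29; neither compares a list with other genes. Named genes followed a rule fixed at the same time: the 15 largest increases and the 15 largest decreases past the threshold with a mean of at least 1 log2 CPM, up to 4 members of smallest p per list, 17 genes set by name and the 5 most abundant. Of these the text gives those that describe each group, and Ccr2, Timd4, Angptl4 and Tcap were named after their values were seen.

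The gene test was run on simulated counts with the means, dispersions and library sizes of these samples and 200 changed genes. Of the changed genes tested, 49.2% were recovered at 1.5-fold, 73.8% at 2-fold and 98.3% at 4-fold, and 5 of 144 calls were false, over 13490 genes. The list test, on 13622 simulated genes, found the 1 raised list of 30 genes and called 0 of 20 unchanged lists. The simulated genes varied independently of each other, so this does not show how the list test behaves where members vary together. With 200 changed genes, against 4455 called in the samples, the recovered shares may also differ from those in these data.

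The alternatives fixed at the same time were DESeq2 1.42.0, RLE and upper quartile factors, library size alone, no filter and a filter of 1 CPM in 5 samples, limma voom with sample weights, no robust estimation, removal of mitochondrial genes or of the 20 most abundant genes, the replicate number as a block, 1 surrogate variable from sva 3.50.0, the 2 other list tests and each library left out in turn. Added after seeing the data were a GC correction, centred and not centred and with the replicate block, the removal of 14 abundant lower features, and naive 1 and sham 4 left out together. All were run in R 4.3.3.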

Results

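Polyadenylated RNA of the heart ventricles was sequenced from 10 male C57BL/6 mice aged 10 weeks. In 5 mice a sham operation for ischemia-reperfusion had been performed, the surgical control for a study of a blocked and reopened coronary artery. The other 5 mice were naive and had no operation. The labels give each library as a separate sample of its group. The comparison asks which transcripts of the ventricle differ after the control surgery itself. The time between the operation and the removal of the heart is not given in the sources used here. Each naive library held 9683181 to 17577906 counted reads and each sham library 10654107 to 21537135, and 20235 to 24214 genes had at least 1 count in a library. A gene with 3 counts stood at 0.139 CPM in the deepest library and at 0.310 CPM in the shallowest. Every pair of libraries of a group differed by at least 9.20 times the sampling noise of counts (chi-square per degree of freedom), so no 2 of them were repeat counts of a single library. That value does not show that they came from separate animals.

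The groups separated on the first principal component of log2 CPM, which held 53.5% of the variance, and the second, with 15.9%, ran within the groups. Scores on the second fell with replicate number, from 38.7 in naive 1 to -28.0 in naive 5. In sham libraries they fell from 16.4 in sham 1 to -14.7 in sham 4, with sham 5 at -9.52. Pearson's r across the 13622 tested genes, which are not independent replicates, was 0.966 to 0.989 among naive libraries, 0.973 to 0.991 among sham libraries and 0.949 to 0.967 between the groups. Protein-coding genes took 84.3% ± 2.69 of the counts in naive and 91.1% ± 3.02 in sham libraries (SD, n = 5, exact two-sided permutation p = 0.0159, 0.0357 after Benjamini-Hochberg adjustment over 9 library measures). The 20 genes with the most counts took 28.3% ± 2.49 in naive and 21.2% ± 2.44 in sham libraries, with the same exact permutation p-values. Most of both differences lay in the same non-coding features, whose counts are uncertain as expression (described below). Gm42418 took 6.61% of counts in naive and 4.07% in sham libraries, Gm14236 3.02% and 1.52%, and Gm23935 4.22% and 1.52%. Mitochondrially encoded genes took 1.90% ± 0.387 and 1.84% ± 0.164 (n = 5, exact permutation p = 0.794). Of these, mt-Co2, mt-Co3 and mt-Atp6 had 0 counts over the 5 naive libraries and 2 to 4 over the 5 sham libraries. By contrast, mt-Co1 was at 2931 CPM in naive libraries. The share may therefore miss reads of some mitochondrial genes, for a reason that was not tested.

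**Figure D1:**
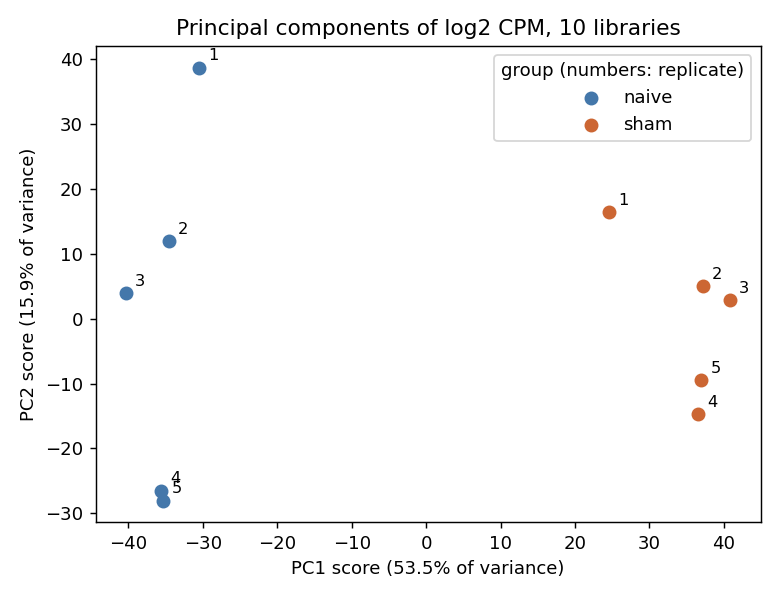
Scores of the 10 libraries on the first principal component (53.5% of variance, horizontal axis) and the second (15.9%, vertical axis) of log2 CPM over 13622 genes, with 1 point per library numbered by replicate. The naive libraries lie at -40.3 to -30.5 on the first component and the sham libraries at 24.6 to 40.9, with sham 1 nearest to the naive group.

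Sham ventricles held more RNA of matrix, acute phase, inflammatory, macrophage and cell cycle genes than naive ventricles, and less RNA of genes for fatty acid use, ion channels and heart muscle markers. As lists, the ion channel genes and the heart muscle markers were lower with a preset correlation but did not pass with an estimated correlation (camera adjusted p = 0.113 for each). Of 13622 genes tested, 2342 were higher and 2113 lower in sham (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). The median fold of the higher genes was 1.81 and that of the lower genes 1.35. At least a 2-fold change was fitted for 994 higher and 75 lower genes, and at least a 4-fold change for 289 higher genes and 1 lower gene. In 1800 of the higher genes all 5 sham libraries lay above all 5 naive libraries. In 1185 of the lower genes all 5 lay below all 5 naive libraries. The balance of higher and lower calls depended on the scaling. With library size alone in place of TMM factors there were 4473 higher and 283 lower genes, 94.0% higher against 52.6%. The median log2 fold change of all tested genes moved by 0.26 with this scaling. A GC correction that was not centred, tried after seeing the data, gave 2014 higher and 3405 lower genes.

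Among the largest increases, haptoglobin (Hp, chromosome 8, 109575128 to 109579172 on the minus strand of GRCm38), the plasma protein that binds free hemoglobin, rose from 2.64 ± 2.02 to 98.2 ± 59.7 CPM (SD, n = 5), a log2 fold change of 5.21 ± 0.62 (SE, adjusted p = 2.76e-04). Saa3, an acute phase serum amyloid protein with close paralogs, rose by 5.21 ± 0.67. The prolyl hydroxylase subunit P4ha3 rose by 4.84 ± 0.22. Osteopontin (Spp1, chromosome 5, 104435118 to 104441050, plus strand) rose from 0.542 ± 0.319 to 16.2 ± 5.57 CPM, a log2 fold change of 4.82 ± 0.37 (adjusted p = 2.22e-07). The collagen triple helix protein Cthrc1 rose by 4.69 ± 0.26 and tenascin C (Tnc) by 4.46 ± 0.25. Also higher were arginase 1 (Arg1) by 4.36 ± 0.41 and Sprr1a by 4.34 ± 0.42. Timp1 (chromosome X, 20870166 to 20874735, plus strand), an inhibitor of matrix metalloproteinases, rose from 4.14 ± 1.09 to 80.4 ± 25.3 CPM. In each of these genes all 5 sham libraries lay above all 5 naive libraries.

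Of the 33 tested genes for extracellular matrix and fibrosis, 32 rose, 0 fell and 1 did not pass (median log2 fold change 2.07, camera adjusted p = 2.68e-27). The count adjusted over the list alone was also 32. With an estimated correlation the list passed at a camera adjusted p of 0.0323. Type I collagen chain Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) rose from 601 ± 156 to 8598 ± 2031 CPM, a log2 fold change of 3.84 ± 0.21 (SE, n = 5, adjusted p = 9.31e-09). Col1a2 rose by 3.32 ± 0.17, Col5a2 by 2.96 ± 0.14, Col14a1 by 2.79 ± 0.12 and the latent TGF-beta binding protein Ltbp2 by 2.93 ± 0.14. The collagen cross-linking enzyme Lox rose by 3.83 ± 0.31 and periostin (Postn), a matricellular protein of activated fibroblasts, from 14.4 ± 5.50 to 173 ± 79.9 CPM. Markers of fibroblasts as a cell type moved less: 13 of 16 rose, 1 fell and 2 did not pass (median 0.54, adjusted p = 2.07e-05, 13 and 1 adjusted over the list alone). Among them were Dpt at 1.24 ± 0.11, Fbln2 at 0.92 ± 0.09 and Mmp2 at 0.70 ± 0.08.

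**Figure D2:**
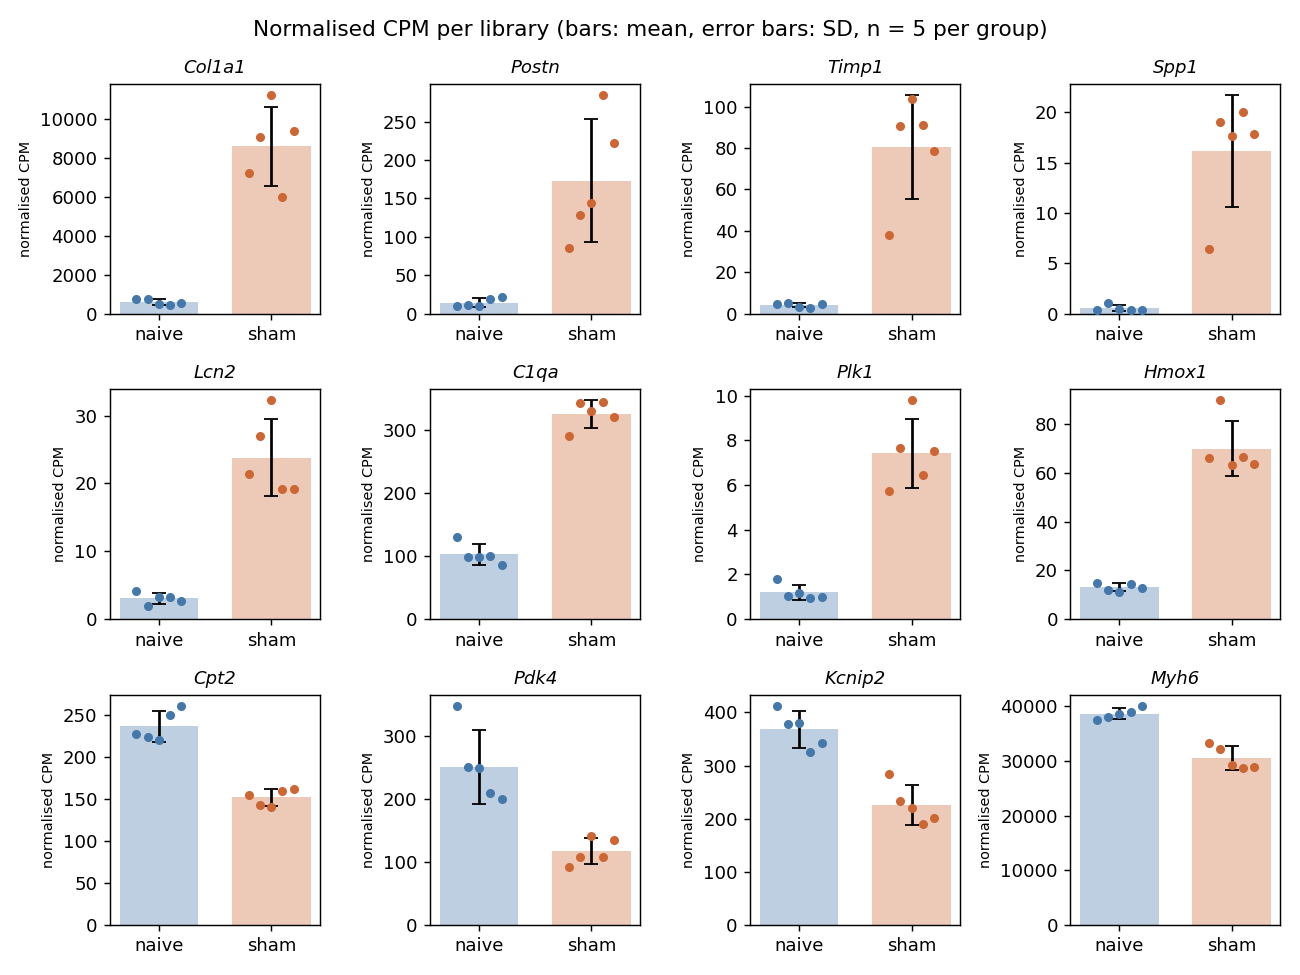
Normalised CPM (vertical axes, linear and from 0) of 12 genes in naive and sham ventricles, with 1 point per library, bars at the mean and error bars of 1 SD (n = 5 per group). Col1a1 reaches 8598 ± 2031 CPM in sham against 601 ± 156 in naive, while Cpt2 lies at 152 ± 9.71 against 236 ± 18.1.

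Inflammatory and acute phase genes were higher as groups. Of 19 tested genes of acute inflammation and cytokine signalling, 16 rose, 0 fell and 3 did not pass (median 1.84, adjusted p = 6.18e-12, 16 adjusted over the list alone). The monocyte chemoattractant Ccl2 rose by 2.43 ± 0.22, the cytokine signalling inhibitor Socs3 by 1.84 ± 0.12, Il4ra by 1.53 ± 0.09 and Il1r1 by 1.46 ± 0.11. Il1b, Il6, Cxcl2 and Ptgs2 were too low to be tested, with 3 to 78 counts over the 5 libraries of a group. Of 11 acute phase and tissue injury genes 10 rose, 0 fell and 1 did not pass (median 3.00, adjusted p = 5.81e-09, 10 adjusted over the list alone). Serpina3n, an acute phase protease inhibitor, rose from 8.96 ± 2.19 to 79.5 ± 14.2 CPM and lipocalin 2 (Lcn2), which binds bacterial siderophores, from 3.05 ± 0.811 to 23.8 ± 5.71 CPM.

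Macrophage and monocyte markers rose in 17 of 20 cases, with 1 lower and 2 not past (median 1.57, adjusted p = 6.86e-12, 18 and 1 adjusted over the list alone). The complement chains C1qa, C1qb and C1qc rose by 1.66 ± 0.11, 1.89 ± 0.10 and 1.57 ± 0.10, and Cd68 by 1.81 ± 0.11. The monocyte receptor Ccr2 was higher by 3.26, whereas Timd4, a marker of resident macrophages, was lower by a log2 fold change of -0.72. Of 4 neutrophil markers 3 rose and 1 did not pass (median 1.73, adjusted p = 0.0161, but adjusted p = 0.254 with an estimated correlation, 3 adjusted over the list alone). Csf3r led them at 2.77 ± 0.24. Of 7 lymphocyte markers 4 rose and 3 did not pass (median 1.37, adjusted p = 0.00532, but adjusted p = 0.0642 with an estimated correlation, 5 adjusted over the list alone). Cd22 was at 2.45 ± 0.28 and Ccl5 at 2.16 ± 0.28.

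Interferon response genes rose in 20 of 25 cases, with 0 lower and 5 not past (median 0.80, adjusted p = 1.11e-08, 22 adjusted over the list alone). This call was lost with an estimated correlation (adjusted p = 0.254). In sham 1 the interferon genes showed a median of 0.273 of the change of the other sham libraries, where 6 other lists showed 0.551 to 0.716. The nucleic acid sensor Zbp1 rose by 3.39 ± 0.33, Oas1a by 2.25 ± 0.28, Oasl2 by 1.72 ± 0.17 and Bst2, which tethers budding virions, by 1.55 ± 0.17. The oligoadenylate synthetases are close paralogs. Of 27 cell cycle genes 25 rose, 1 fell and 1 did not pass (median 1.72, adjusted p = 1.18e-13, 25 and 1 adjusted over the list alone). With an estimated correlation this list was just past the threshold (camera adjusted p = 0.0491). The mitotic kinase Plk1 rose from 1.19 ± 0.342 to 7.42 ± 1.55 CPM, topoisomerase Top2a by 2.40 ± 0.21, Birc5 by 2.81 ± 0.28 and the replication helicase subunit Mcm5 by 1.85 ± 0.14. The 1 lower member was the cyclin Ccne2, at 560 ± 102 CPM in naive and 178 ± 46.7 in sham libraries. It shares 17.4% of its exon bases with Ints8 and is among the abundant lower features described below, so its value is uncertain.

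Genes of the unfolded protein and integrated stress response were higher in 12 of 24 cases, lower in 1 and not past in 11 (median 0.34, adjusted p = 8.71e-04, but adjusted p = 0.254 with an estimated correlation, 14 and 2 adjusted over the list alone). The members with the smallest p make amino acids or one-carbon units: Mthfd2 rose by 1.65 ± 0.22, asparagine synthetase (Asns) by 1.41 ± 0.25, Phgdh, of serine synthesis, by 2.03 ± 0.39 and Aldh18a1, of proline synthesis, by 0.92 ± 0.13. Cytosolic ribosomal proteins were higher in 14 of 34 cases, lower in 0 and not past in 20 (median 0.35, adjusted p = 1.70e-04, but adjusted p = 0.471 with an estimated correlation, 14 adjusted over the list alone). They included Rpl3 at 0.72 ± 0.11 and Rps19 at 0.68 ± 0.14. Reads of ribosomal protein genes can be shared with their many pseudogenes, so these values are uncertain.

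Genes of fatty acid use and PPAR targets were lower in 23 of 29 cases, higher in 1 and not past in 5 (median -0.53, adjusted p = 2.28e-07, 24 lower and 1 higher adjusted over the list alone). Cpt2 (chromosome 4, 107903981 to 107923610, minus strand), which readies fatty acids for oxidation inside mitochondria, fell from 236 ± 18.1 to 152 ± 9.71 CPM, a log2 fold change of -0.64 ± 0.08 (SE, n = 5, adjusted p = 1.84e-05). Etfdh changed by -0.61 ± 0.08, Acot2 by -0.57 ± 0.08 and Pdk4, the kinase that restrains pyruvate oxidation, by -1.11 ± 0.15. The 1 higher member was Angptl4, an inhibitor of lipoprotein lipase, at 1.24. Nuclear genes of the respiratory chain were lower in 22 of 41 cases, higher in 0 and not past in 19 (median -0.35, adjusted p = 1.46e-07, but adjusted p = 0.363 with an estimated correlation, 29 lower adjusted over the list alone). Uqcrc1 was at -0.47 ± 0.09 and Cyc1 at -0.42 ± 0.09. Of 9 tested mitochondrially encoded transcripts (15 were listed, and the others were too low to be tested), mt-Nd5 was lower (-0.29 ± 0.10). The other 8 did not pass, with 0 adjusted over the list alone. These counts depended on single libraries: without sham 4, 35 respiratory chain genes and 4 mitochondrial transcripts were lower, and without naive 1 also 4 of the latter. The mt-Nd5 transcript did not pass without naive 2 or 5 or sham 2 or 5 (adjusted p of 0.0582 to 0.114). Without sham 2, 3 or 5, 15 respiratory chain genes were lower. With the replicate number as a block the counts were 34 of 41 and 4 of 9. The list of mitochondrial transcripts was just past the threshold (median -0.29, adjusted p = 0.0456) and was not with an estimated correlation (adjusted p = 0.537). The glycolysis list did not pass (adjusted p = 0.0715) but did without a filter (adjusted p = 0.0170), with the GC correction added after seeing the data (adjusted p = 0.0353), without naive 1 (adjusted p = 0.0494) and without sham 4 (adjusted p = 0.0244). It had 3 of 23 members higher, 8 lower and 12 not past (3 and 11 adjusted over the list alone). Eno1 rose by 0.68 ± 0.10 and Pfkfb3 by 0.78 ± 0.14. Pfkfb2, a heart form of the same bifunctional enzyme family, changed by -1.02 ± 0.13 and the glucose transporter Slc2a4 by -0.47 ± 0.09.

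Ion channel and calcium handling genes were lower in 21 of 28 cases, higher in 0 and not past in 7 (median -0.46, adjusted p = 2.29e-06, but adjusted p = 0.113 with an estimated correlation, 22 lower and 1 higher adjusted over the list alone). Kcnip2, a subunit of the channel that carries the transient outward potassium current, fell from 368 ± 34.4 to 226 ± 36.9 CPM. Its partner Kcnd2 changed by -0.86 ± 0.15, the sodium channel subunit Scn4b by -0.77 ± 0.08 and the ryanodine receptor Ryr2 by -0.66 ± 0.13. Heart muscle markers were lower in 16 of 20 cases, higher in 1 and not past in 3 (median -0.41, adjusted p = 6.82e-06, but adjusted p = 0.113 with an estimated correlation, 17 and 1 adjusted over the list alone). Myoz2 changed by -0.53 ± 0.09, Ckm by -0.50 ± 0.09 and Actn2 by -0.42 ± 0.08. The 1 higher member was Tcap at 0.57. Heat shock and chaperone genes were lower in 12 of 21 cases, higher in 0 and not past in 9 (median -0.41, adjusted p = 1.92e-04, but adjusted p = 0.128 with an estimated correlation, 12 adjusted over the list alone). Among them Dnajb5 changed by -0.65 ± 0.07 and the small heat shock proteins Hspb8 and Hspb6 by -0.56 ± 0.10 and -0.53 ± 0.10. Dnaja4, at -0.67 ± 0.10, shares exon sequence with Wdr61 on the other strand. With library size alone these lists kept negative medians (-0.26 for fatty acid use, -0.20 for ion channels, -0.15 for both heart muscle and heat shock, -0.09 for the respiratory chain and -0.03 for mitochondrial transcripts). The lower members past the threshold then numbered 10, 6, 3, 3, 0 and 0.

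The cardiac stress and fetal gene programme did not pass as a list (median 0.21, adjusted p = 0.356), with 6 of 16 members higher, 1 lower and 9 not past, alike adjusted over the list alone. Beta myosin heavy chain (Myh7) rose by 0.36 ± 0.10 and alpha myosin heavy chain (Myh6) fell from 38652 ± 998 to 30509 ± 2147 CPM. Atrial natriuretic peptide (Nppa) was at 45.2 ± 6.10 CPM in naive and 82.3 ± 34.5 in sham libraries (log2 fold change 0.87 ± 0.27, adjusted p = 0.0309). It did not pass without naive 2, 3, 4 or 5 or without sham 5 (adjusted p of 0.0565 to 0.0794), nor with the replicate number as a block (adjusted p = 0.141). Of its exon bases, 61.5% overlap an antisense gene, from which unstranded reads cannot be told apart. Nppb was at -0.39 ± 0.19, Ankrd1 at 0.46 ± 0.22 and Acta1 at -0.30 ± 0.22, none past the threshold. With the replicate block Nppb passed as lower (adjusted p = 0.00285) and Ankrd1 as higher (adjusted p = 0.00510), and 3 members of the list were lower. The stress genes Bcl3 and Cdkn1a rose by 0.96 ± 0.13 and 0.76 ± 0.13.

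**Figure D3:**
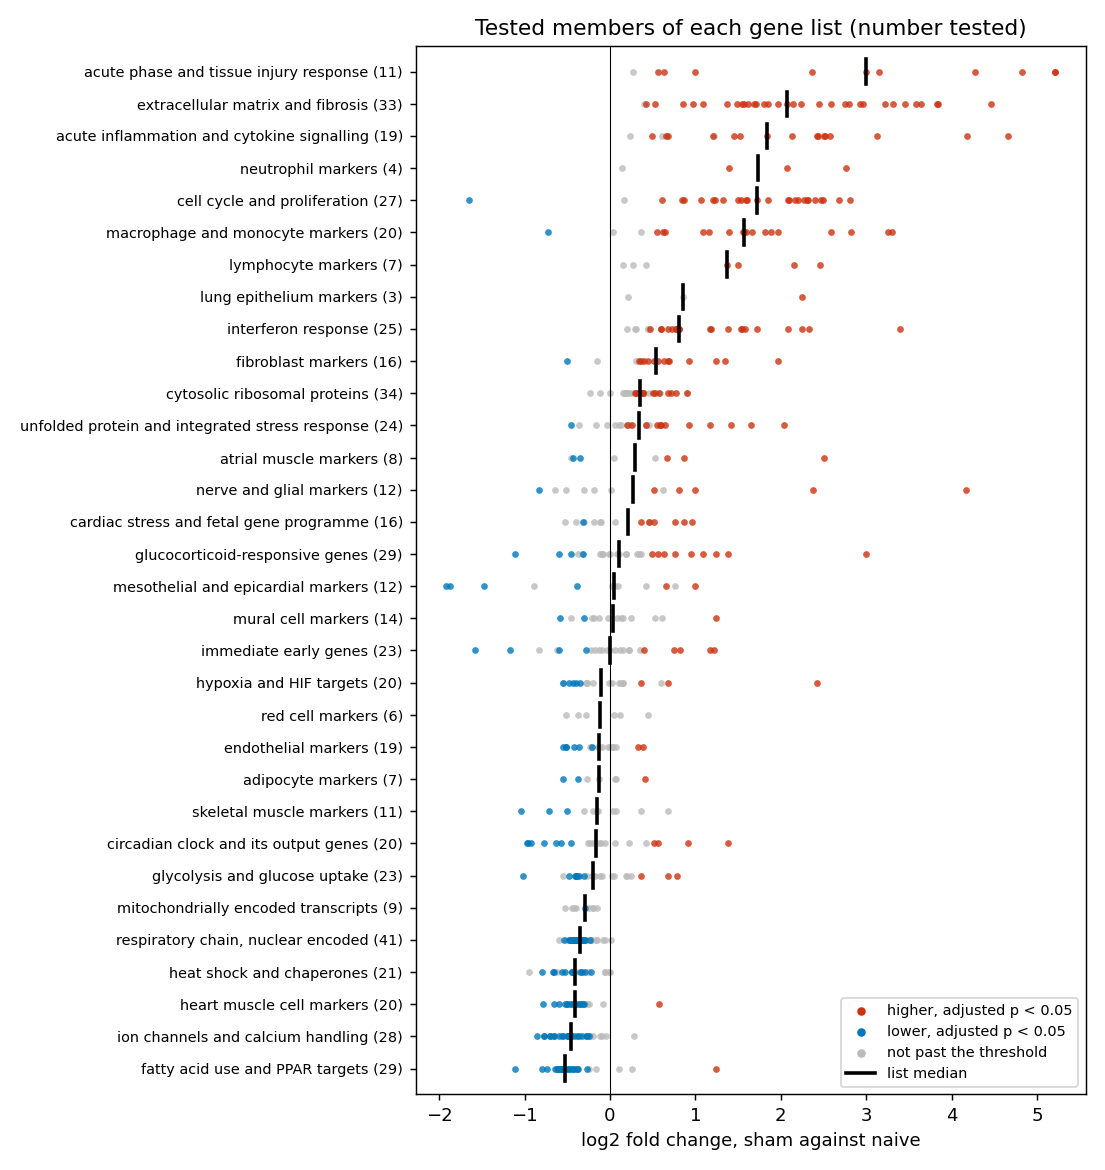
Log2 fold change of sham against naive (horizontal axis) for each tested member of the 32 gene lists (rows, sorted by median, with the number of members tested), where points are genes coloured by the edgeR call and black bars are list medians. Medians run from 3.00 for the acute phase list to -0.53 for the fatty acid list, and with library size alone the medians from the hypoxia list down to the glycolysis list turn positive.

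Clock and stress hormone genes went both ways. Of 20 circadian genes 4 rose, 7 fell and 9 did not pass, with the same numbers adjusted over the list alone (median -0.16, adjusted p = 0.231). With library size alone the list passed (camera adjusted p = 0.0459), its test still pointing down though its median was 0.10. The clock output factor Dbp rose from 38.5 ± 7.91 to 101 ± 30.2 CPM and Per1 by 0.57 ± 0.13. Cry1 changed by -0.97 ± 0.15, Nfil3 by -0.78 ± 0.10 and Arntl by -0.45 ± 0.13. Glucocorticoid-responsive genes did not pass as a list (median 0.11, adjusted p = 0.125, but adjusted p = 0.0470 without naive 4; 9 of 29 higher, 4 lower and 16 not past, alike adjusted over the list alone). The receptor co-chaperone Fkbp5 rose by 0.95 ± 0.13 and Cebpd by 1.09 ± 0.16. Immediate early genes did not pass either (median 0.00, mean -0.01, test pointing up, adjusted p = 0.567; 5 of 23 higher, 4 lower and 14 not past, alike adjusted over the list alone). Myc rose by 1.22 ± 0.17 and Egr2 by 1.17 ± 0.17. The nuclear receptors Nr4a1 and Nr4a3 changed by -1.58 ± 0.37 and -1.17 ± 0.25. Fos and Egr1 were at -0.83 ± 0.58 and -0.62 ± 0.35, not past. Egr1 passed with the replicate block (adjusted p = 0.0213), and Fos passed with limma voom (adjusted p = 0.0496). Among 20 hypoxia genes 3 rose, 5 fell and 12 did not pass, alike adjusted over the list alone (median -0.10, mean 0.04, test pointing down, adjusted p = 0.607). Heme oxygenase (Hmox1, chromosome 8, 75093621 to 75100589, plus strand) rose from 13.1 ± 1.65 to 70.0 ± 11.2 CPM. Vegfa and Hk2 were lower, at -0.54 ± 0.11 and -0.40 ± 0.08.

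The remaining cell type lists did not pass. Endothelial markers had 2 of 19 higher, 6 lower and 11 not past (median -0.13, adjusted p = 0.159; 2 and 7 adjusted over the list alone). The 6 lower ones were 3 without naive 4 or 5 or sham 2, 3 or 4. Kdr was at -0.55 ± 0.10 and Vwf at 0.33 ± 0.09. Mural cell markers had 1 of 14 higher, 2 lower and 11 not past, alike adjusted over the list alone (median 0.03, adjusted p = 0.874). The lower mural markers were Abcc9 at -0.58 ± 0.15 and Kcnj8 at -0.30 ± 0.09, which did not pass without sham 2, 3 or 5. Tagln was at 1.24 ± 0.17 and shares most of its exon bases with others on the opposite strand. Mesothelial and epicardial markers went apart, with 2 of 12 higher, 4 lower and 6 not past (median 0.05, mean -0.29, test pointing down, adjusted p = 0.589; 3 and 5 adjusted over the list alone). The uroplakin Upk3b fell from 17.7 ± 3.23 to 4.84 ± 1.88 CPM. Lrrn4 and Rspo1 changed by -1.47 ± 0.29 and -1.92 ± 0.44, while complement C3 rose by 0.99 ± 0.17. Nerve and glial markers had 5 of 12 higher, 1 lower and 6 not past (median 0.26, adjusted p = 0.429; 5 and 2 adjusted over the list alone). The axon growth protein Gap43 rose from 0.0879 ± 0.0684, below the level of 3 counts, to 1.73 ± 1.18 CPM, and Tubb3 by 2.38 ± 0.22, whereas Dbh, of noradrenaline synthesis, changed by -0.83 ± 0.22. Atrial markers (3 of 8 higher, 2 lower, adjusted p = 0.542; 4 and 3 adjusted over the list alone), adipocyte markers (1 of 7 higher, 2 lower, adjusted p = 0.483; 1 and 3), skeletal muscle markers (0 of 11 higher, 3 lower, adjusted p = 0.202; 0 and 3), lung epithelium markers (1 of 3 higher, 0 lower, adjusted p = 0.118; 2 and 0) and red cell markers (0 of 6 higher or lower, adjusted p = 0.878; 0 and 0) did not pass. Among the atrial markers Dkk3 rose by 2.51 ± 0.20, and the median of the red cell list was negative (-0.11) where its test pointed up.

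Several of the largest decreases were in features with high counts. Gm23935, listed as a microRNA gene (chromosome 16, 11144125 to 11144181, plus strand), was at 46624 ± 9836 CPM in naive and 13837 ± 5270 in sham libraries. Gm14236, listed as antisense, was at 33503 ± 11775 and 13938 ± 3380, and Pnck at 15050 ± 6996 and 5484 ± 1060. Cadps2 and Ube3c changed by -1.53 ± 0.14 and -1.53 ± 0.17. The counts cannot tell reads of these genes from reads of near-identical or structural RNA placed there, so the values are uncertain as expression of the named genes. Gm42418, the most abundant feature, was at 72949 ± 25449 and 37824 ± 28233 CPM and did not pass (adjusted p = 0.165), but passed without sham 4 (-1.46, adjusted p = 0.0116) and with the replicate block (adjusted p = 0.00133). Of its exon bases, 99.5% overlap other annotated genes.

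In all, 11 of the 32 lists were higher, 6 were lower and 15 were not past with the preset correlation, and 7 passed with an estimated correlation: acute inflammation, acute phase, extracellular matrix, fatty acid use, cell cycle, fibroblast and macrophage lists. For these 7 the camera adjusted p was 2.68e-27 to 2.07e-05 with the preset correlation. With an estimated correlation it was only 0.0323 to 0.0491, the highest for the cell cycle list. In an exact test added after seeing the data, over the 126 splits of the libraries into 5 and 5, the real split gave the largest difference between a list's median and that of all genes for 13 lists (exact p = 0.00794, the smallest possible, 0.0195 adjusted over 32 lists): the 11 higher lists without interferon response, and fatty acid use, ion channel and heart muscle lists. The other lists that were higher or lower with the preset correlation did not pass this exact test: interferon response (3 of 126 splits as large, adjusted p = 0.0508), respiratory chain and heat shock (adjusted p = 0.0598 for each) and mitochondrial transcripts (adjusted p = 0.181). The exact test exchanges the libraries freely and takes no account of any pairing by replicate number.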

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

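The splits for lists with an estimated correlation, the comparison of endothelial with macrophage markers and the test of interferon genes in sham 1 were chosen only after the result was seen. Of 100 splits of the 10 libraries into 5 and 5, drawn from 126, only the real one (1 of 100) gave as many as 2342 higher genes, and the same holds for 2113 lower genes (1 of 100). The highest other gave 1 gene in each case, so chance is argued against for both counts, at the smallest share that 100 splits allow. In mixed splits the difference between the groups becomes spread within each side, which by itself keeps their counts low. For the 17 lists with the preset correlation, 13 of the 100 splits gave at least as many, the highest other 19. This count cannot decide about chance, because unevenly mixed splits keep part of the difference between the groups, through which lists can pass. The extracellular matrix median lay 2.097 from that of all genes in the real split and up to 1.506 in another. For macrophage markers these values were 1.601 and 1.067. With an estimated correlation 7 lists passed in the real split (1 of 100) and at most 0 in the others. This argues against chance for that count with the same limit, since in mixed splits the difference between the groups also raises the estimated correlation.

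A library stood apart from the other 4 of its group in 31 of 340 groups of values tested, where chance gives about 17. Sham 4 had 2.12% of counts in mitochondrial genes, where the other sham libraries had 1.71% to 1.80%. It also had 0.221% in genes listed as rRNA, where the others had 0.0176% to 0.0491%. Naive 4 had 10.4% of counts in Gm42418, where the other naive libraries had 5.11% to 6.55%. Of the 31 cases 28 were in genes, and sham 1 was the library in 10 of these 28 cases. It was below the other sham libraries for Spp1 (6.41 CPM, others 17.6 to 20.1), Timp1 (38.0), Bst2 (45.3), Oas1a (2.69), Top2a (6.24), Tubb3 (4.85) and Acta1 (335). It was above them for Slc2a4 (644 CPM), Lpl (2475) and Dbp (154). Sham 2 was low for Ccne2 (96.4 CPM) and high for Hmox1 (89.9), and sham 3 was high for Sfrp2 (151) and Csf3r (27.3). Sham 4 was low for Ryr2 (907 CPM) and Abcc9 (129) and high for Bpgm (12.5), and sham 5 was low for Cebpd (47.0) and high for Nfil3 (17.7). Naive 1 was high for Actn2 (3489 CPM), Stard10 (71.3), Fbln2 (268) and C1qc (149). Naive 2 was high for Spp1 (1.11 CPM) and Dbp (52.4) and low for Ccl2 (2.21), naive 3 was high for Ccl5 (1.66) and naive 5 for S100a9 (1.26).

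Sham 1 lay nearest to the naive group and, over 1033 genes at least 2-fold higher in the fit without it, showed a median of 0.686 of the change of the other sham libraries, against 0.938 to 1.16 for each of the others by the same measure. Sham 2 thinned at random to the total of sham 1 showed 1.02 of the change (95% bootstrap interval 1.00 to 1.04). Random thinning keeps the expected proportions, so a value near the 1.01 of sham 2 itself was set in advance. It shows only that fewer reads do not by themselves shrink this median, and other faults of a shallow library were not tested. Naive RNA mixed in as the whole cause would leave interferon genes at the same fraction as the other higher genes. In sham 1 they lay a further -0.42 (-0.57 to -0.34) below these. Interferon genes were the most extreme of 7 lists (0.273, others 0.551 to 0.716). The interval rests on 11 interferon genes of 1 library that vary together (estimated correlation 0.503), and it leaves out the spread between mice. So the gap does not decide whether a mixture was the whole cause. In sham 1 Acta1 (335 CPM) and Nppb (60.8) lay below all other libraries of both groups and Dbp (154) above them. These values do not decide about a mixture, which bounds a gene only by naive RNA and by the unknown sham RNA of this mouse. Acta1 and Nppb did not pass between the groups either, and these genes were picked from many. Naive RNA mixed in, as a part or the whole of the cause, stays open. The fractions of higher and lower genes differed by only -0.0148 (-0.0402 to 0.0156). The 2153 lower genes were taken at any size of change and the higher genes at 2-fold or more, so the 2 sets were not chosen alike. A milder response in this mouse stays open too and was not tested.

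Heart muscle markers were lower while macrophage markers were higher, though the decreases of heart muscle markers and of ion channel genes did not pass with an estimated correlation (adjusted p = 0.113 for each). A loss of heart muscle RNA with nothing else changed would raise the markers of other cell types alike. The endothelial median lay -1.69 (95% bootstrap interval over members -1.99 to -0.99) from the macrophage median, which argues against such a loss as the whole cause. This comparison cannot exclude a lower share of heart muscle RNA through added RNA of some other cell types, which need not raise endothelial markers. A lower share may still account for the ion channel decrease. The median of that list differed from that of heart muscle markers by -0.0459 (-0.167 to 0.121) without shared members. For the fatty acid list the difference was -0.11 (-0.217 to 0.0166), an interval too wide to decide. An effect of the operation within the muscle cells was not tested.

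The 14 abundant features that were lower in sham (more than 8 log2 CPM, lower by more than 0.9, whatever their p) include Gm42418, Gm23935, Gm14236 and Pnck. GC content is argued against, as their median log2 fold change was -1.25 before and -1.26 after the centred GC correction. Reads of a single RNA source would keep their ratios to Gm42418 steady between libraries of a group. The median SD of the log2 ratio was 0.745, against a median of 0.785 for random sets of other abundant genes. A share of 0.124 of 10000 sets was as low, so this stays undecided for the 14 as a set. Some single ratios were far from steady. In sham 4 Gm42418 took 8.87% of counts and Gm23935 0.7004%, against 1.96% and 1.37% in sham 2. In naive 1 Gm42418 took 5.11% and Gm14236 4.47%, against 10.4% and 2.59% in naive 4. These features were picked from the 14, so they do not decide about the others. No biological explanation was tested.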

How the results depend on the processing

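The GC corrections, the removal of 14 abundant features and the joint removal of naive 1 and sham 4 were chosen after seeing the data. No gene called in one direction by the main test was called in the other under any alternative. The alternatives were not compared with each other in this way. The medians of 7 lists, none past the threshold with TMM factors, turned from negative to positive with library size alone, among them glycolysis (-0.19 to 0.07) and circadian genes (-0.16 to 0.10). Higher genes were 52.6% of the calls with TMM factors, 48.1% with the replicate block and 37.2% with the uncentred GC correction. Library size alone gave 4473 higher and 283 lower genes, including 2342 and 283 of the genes called with TMM factors, as the median fold change of all genes moved up by 0.26 log2. Limma voom gave 3269 lower genes, for a reason that was not tested. The uncentred GC correction, the first version tried, gave 3405 lower genes and 4143 with the replicate block; it also moved the median of all genes by -0.08, and it was replaced by a centred version after these counts were seen. The centred version gave 2379 higher and 2282 lower genes, or 2650 and 2950 with the replicate block. An estimated correlation left 7 of 17 lists past the threshold, as that test allows for members that vary together. Leaving out 1 library in turn gave 2132 to 2461 higher genes and 1465 (without sham 2) to 2249 lower genes. Without naive 1 and sham 4 there were 2594 higher and 2131 lower genes, and without the 14 abundant features 2331 and 2107.

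The replicate number as a block gave 2592 higher and 2801 lower genes, with 34 of 41 respiratory chain genes lower (22 without it), 4 of 9 mitochondrial transcripts (1), 8 of 20 hypoxia genes (5) and 3 of 16 cardiac stress genes (1). The labels do not say that a number marks a shared day or batch. The deviations of same-numbered libraries correlated by 0.01 to 0.29, above 0.1 in 3 of 5 pairs. In these 3 pairs, numbered 1, 4 and 5, both libraries matched best with their own number (6 of 10 libraries). Scores on the second principal component also fell with replicate number in both groups, apart from sham 5. So the numbers are a hint of pairing from the data, not the design, and the main test takes no account of it.

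Of 161 named genes, 112 kept their direction and side of the threshold under every alternative; 27 lower ones were no longer past it with library size alone, among them Slc2a4, Uqcrc1, Cyc1, mt-Nd5, Hspb6, Ckm, Actn2, Kdr, Dbh, Myh6, Arntl, Vegfa, Hk2, Abcc9 and Kcnj8. Arntl was also lost without naive 1 and sham 4, and Myh7 and Vwf with the uncentred GC correction. Of 32 lists, 27 kept their call under every alternative other than the 2 other list tests. Mitochondrial transcripts were no longer past the threshold with upper quartile factors (adjusted p = 0.0530), without a filter, with GC correction or without naive 4 or 5 or sham 1, 2, 3 or 5. The glycolysis list passed without a filter, with GC correction and without naive 1, sham 4 or both. The glucocorticoid list passed without naive 4 (adjusted p = 0.0470), and the circadian and skeletal muscle lists passed with library size alone (adjusted p = 0.0459 for each). For these 2 lists the test still pointed down. Their medians of 0.10 and 0.11 were positive but below the 0.22 of all genes with that scaling. Leaving out 1 library moved some counts of list members by over 1.5 times. Lower endothelial markers fell from 6 to 3 without naive 4 or 5 or sham 2, 3 or 4, lower hypoxia genes from 5 to 3 without sham 2 or 5, lower atrial markers from 2 to 0 without sham 5 and lower skeletal muscle markers from 3 to 1 without naive 3. Higher nerve markers fell from 5 to 3 without naive 2, 3 or 5. Lower respiratory chain genes rose from 22 to 35 without sham 4, and lower mitochondrial transcripts from 1 to 4 without naive 1 or sham 4. At this depth and n, the simulation recovered 49.2% of 1.5-fold changes, so genes not past the threshold may still differ by that much.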

Other observations

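The tests of symbol families and of clock phases were chosen only after the result was seen, and the bound of the clock test was revised after its first outcome. Grouping protein-coding genes by the letters before the first digit of their symbol gave 142 families of at least 10 tested members. Of these, 6 held more higher genes than the 18.0% of all 12797 protein-coding genes (one-sided Fisher's exact test, Benjamini-Hochberg over the 142), though genes of a family are not independent. Collagens (Col) rose in 22 of 37 cases (adjusted p = 3.06e-06), led by Col24a1, and fell in 3: Col4a3, Col4a4 and Col22a1. CC chemokines (Ccl) rose in 10 of 13 cases (adjusted p = 2.79e-04), led by Ccl8 and Ccl12, and so did the interferon-inducible Ifi genes (adjusted p = 2.79e-04), led by Ifi206. Matrix metalloproteinases (Mmp) rose in 8 of 11 cases (adjusted p = 0.00379), with Mmp3 at the top and Mmp15 lower, and the replication helicase genes (Mcm) in 7 of 10 (adjusted p = 0.0124). The Rps family rose in 14 of 35 cases (adjusted p = 0.0445) but holds ribosomal kinases as well as ribosomal proteins.

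No family passed for decreases. The lowest p-values were for calcium channel subunits (Cacna, 6 of 10 lower, unadjusted Fisher's exact p = 0.00198, adjusted 0.222), coenzyme Q synthesis genes (Coq, 6 of 11 lower, adjusted 0.222) and phosphodiesterases (Pde, 9 of 22 lower and 3 higher, adjusted 0.222).

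Another time of day of collection is a candidate explanation for the clock genes. Genes of the phase of Arntl (6) would then move against those of the phase of Dbp (12). Their medians were -0.70 and 0.00, a difference of 0.70 (exact permutation over members, p = 0.0310), but the second did not lie above 0 (95% bootstrap interval -0.18 to 0.54), and Hlf (-0.57) and Wee1 (-0.96), placed with Dbp, were lower. Collection times are not given in the sources used here, so time of day and an effect of the operation on clock genes cannot be told apart.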
